A study of Homo sapiens with 16 samples.

How the data were processed

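Human erythroid cells labelled adult or cord blood were measured by ribosome profiling and by RNA-seq, 4 libraries per group and 16 libraries in all. The deposited values were whole-number read counts per gene, not normalized, in 1 table for the whole series, as the values of the file show. Per the submitters' processing notes the authors used cutadapt and STAR and the genome build hg19. No versions are given there, and the annotation, the counting tool, its treatment of reads that fit several genes and its use of strand are not given in the sources used here. Every deposited footprint count was even (0 odd values in the 8 libraries), so a footprint read appears to have been counted 2 times, and a floor of 3 reads was taken as 6 deposited counts. Counts were nevertheless tested as deposited, and division by 2 was run as an alternative. Library columns were matched to samples by name, and 0 columns of per-sample values were left unused.

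The table held 26475 gene rows. Of these 108 were removed before any fit (Y-linked genes, XIST and TSIX). Symbols were compared with RefSeq genes of GRCh38.p14, used for names and gene types only, so no coordinates are given. By current symbol 23749 rows matched, and by current or older symbol 25369 (95.8%).

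Differences between cord and adult libraries were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with filterByExpr, TMM normalization and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p threshold of 0.05. RNA and footprints were fitted separately with 8 libraries each and no covariate. Translational efficiency was the interaction of assay and origin in a fit of all 16 libraries, with the 8 samples as blocks. Footprints against RNA within samples was the assay effect of the same fit, averaged over both origins. The pairing of footprint and RNA libraries comes from the series design text. Within a group, deviations of the 2 libraries of a sample over 4148 genes correlated from -0.102 to 0.262 in adult and from -0.00891 to 0.0529 in cord samples. The fit with no replicate block gave 59 genes for efficiency and 8523 within samples, and its other values stand beside a result where a call changed. Fits with the replicate number of the labels as a block are given with the other alternatives. Standard errors of log2 changes were derived from the F statistic, and intervals of efficiency used the t quantile at a 95% level. CPM used TMM library sizes, and log2 CPM a prior count of 2. A group with 0 counts was given a lower bound on the fold against the floor of 3 reads over the group, which was 0.0335 CPM in cord RNA, 0.0319 in adult RNA, 0.572 in cord footprints and 0.941 in adult footprints, or 0.369 over all 8 footprint libraries. Groups with 1 to 3 reads were given a ratio with an exact (Clopper-Pearson) 95% interval. These exact intervals and the floors cover counting error only, whereas the intervals of efficiency also include the spread between libraries. The 95% intervals of a slope and of medians given further below came from a bootstrap over genes. Shares of counts were compared by a two-sided exact permutation test.

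Before the data were examined, 28 gene lists were fixed, and the tests, the alternatives and the rule for naming genes with them. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in a single direction without comparing them with other genes, were alternatives. Where a list's call was lost with an estimated correlation, that p is given beside it, and the other called lists kept their calls. The list of mitochondrially encoded genes had no measured member (1 list). The lists were: globins, regulators of globin switching, the LIN28B and let-7 target program, heme synthesis, iron uptake and storage, red cell membrane and skeleton, erythroid transcription factors, late erythroid maturation, early progenitor genes, glycolysis and red cell energy, translation factors with a 5' TOP motif, ribosome biogenesis, integrated stress response genes, protein folding, proteasome, cell cycle, interferon response, cholesterol synthesis, mitochondrial ribosome, cytosolic ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, replication-dependent histones, and markers of megakaryocytes, of granulocytes and monocytes, of mast cells, basophils and eosinophils, of macrophages and of lymphoid cells. Key genes could be members of several lists. The list of translation factors with a 5' TOP motif also held genes that are not translation factors, such as VIM, NAP1L1, TPT1 and NPM1. It is called the TOP list below.

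Named genes were 18 key genes, in each comparison the 6 genes of largest fitted change per direction with an adjusted p under 0.05, at least 5 CPM and groups that did not overlap, and up to 4 members per list of smallest adjusted p, given in the text where called. HLA, immunoglobulin and T cell receptor genes, and a fixed list of some blood group and copy-number genes that does not cover all such genes, were never named. Where a list had 5 or fewer members called in a direction, these are named as well, and those outside the rule were chosen after their values were seen. Some genes that these rules would name are not reported here. Genes with near-identical copies or pseudogenes (alpha- and gamma-globins, ribosomal proteins, histones, HSPA1A, TPSB2, metallothioneins) are uncertain.

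Alternatives were RLE size factors, no filter for low counts, globins left out of library sizes, DESeq2 1.42.0 (Wald test), the replicate number as a block, a fit of all 16 libraries for the comparisons within an assay and each replicate left out in turn. Footprint counts divided by 2 and protein-coding genes alone were added after seeing the data. RNA libraries held 17510586 to 29233905 counts and footprint libraries 1475142 to 2869288 deposited counts, so footprint values are the less precise. On simulated counts with known changes, the share recovered at a log2 change of 0.5, 1 and 2 was 40%, 90% and 100% in RNA (13164 genes), 26%, 74% and 98% in footprints (9532 genes) and 8%, 52% and 86% in efficiency (13307 genes). False calls were 5.17%, 7.45% and 8.89% of calls. Of simulated lists with no shift, 2.5% had a camera p under 0.05. Genes were simulated independently and these lists drawn at random, so correlation between the genes of a real list was not covered. No pair of replicates of a group agreed within sampling noise (chi-square per gene 1.21 to 115), so none was merged as 1 library deposited 2 times, which does not show that they came from separate donors. Figures were drawn with matplotlib 3.10.9.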

Results

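Ribosome profiling and RNA-seq were compared between human erythroid cells labelled adult and human erythroid cells labelled cord blood. Ribosome profiling sequences the short messenger RNA fragments that ribosomes shelter from nuclease, so its reads, called footprints, count ribosomes on each gene. Each of the 4 groups (adult or cord, footprints or RNA) held 4 libraries, 16 in all, and each of the 8 samples had a footprint library and a matching RNA library. The RNA libraries held 17510586 to 29233905 gene counts. The footprint libraries held 1475142 to 2869288 deposited counts, every one of which was even. The series title names the question, which is whether the RNA-binding protein LIN28B acts on the translation of BCL11A, a repressor of the fetal globin genes, during hemoglobin switching. The labels do not say that the replicates came from separate donors, so the p-values measure only the spread between these samples, which may be technical. They also do not give the day of differentiation. Differences by origin therefore cannot be told apart from differences in maturation or in the mixture of cells. All directions are cord relative to adult, CPM are normalised, and where a call is said to be lost, gained or kept the value in parentheses is its adjusted p.

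Fetal beta-like globins made up a larger share of the beta-like globin messages in cord than in adult cells. The gamma-globins HBG1 and HBG2, the fetal beta-like chains, made up 51.39% ± 1.99 (SD, n = 4) of the beta-cluster RNA counts in cord libraries and 7.123% ± 0.338 in adult libraries. Among footprints the same share was 27.83% ± 0.655 in cord and 3.274% ± 0.155 in adult libraries. All globins together took 2.258% ± 0.235 of cord and 7.101% ± 1.07 of adult RNA counts, and 2.248% ± 0.0586 against 6.908% ± 0.139 of footprints. In each of these 4 comparisons the groups did not overlap, and the two-sided exact permutation p was 0.0286, the smallest that 4 against 4 libraries can give, or 0.0352 after adjustment over the 16 shares compared.

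By gene, HBB, the adult beta chain, stood at 61410 ± 15300 CPM (SD, n = 4) in adult and 8098 ± 627 CPM in cord RNA, a log2 change of -2.92 ± 0.172 (SE, adjusted p = 1.89e-06). HBD, the minor adult chain, changed by -2.29 ± 0.087. The embryonic chains were higher in cord: HBZ rose from 14.5 ± 5.28 to 259 ± 31.7 CPM and HBE1 from 9.17 ± 0.627 to 25.5 ± 2.44 CPM. HBG2 was also higher in cord RNA, with 8188 ± 1200 against 3371 ± 595 CPM (log2 1.28 ± 0.148, adjusted p = 0.000134). HBG1 did not pass the test in RNA (log2 -0.34 ± 0.155, adjusted p = 0.113; 1249 ± 201 CPM in cord, 1579 ± 308 in adult). In footprints HBG1 was higher in cord, at 1564 ± 60.4 against 1014 ± 14.2 CPM (log2 0.63 ± 0.0595, adjusted p = 1.79e-08), as was HBG2 at 4090 ± 68.2 against 1371 ± 105. HBB footprints changed by -2.30 ± 0.0406, from 66560 ± 1430 in adult to 13510 ± 484 CPM in cord. The alpha chains HBA1 and HBA2 were lower in cord RNA (log2 -1.09 ± 0.153 and -0.70 ± 0.188). Their footprints were few and did not pass the test (adjusted p = 0.429 and 0.199). The HBA2 call in RNA was lost without cord replicate 1 (adjusted p = 0.0518) or cord replicate 2 (0.0536). HBG1 and HBG2 are near-identical, as are HBA1 and HBA2. How reads were divided within each pair, and whether shared reads were counted at all, is uncertain. The sizes of the gamma-globin and all-globin shares, and their differences between RNA and footprints, are therefore uncertain too.

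**Figure D1:**
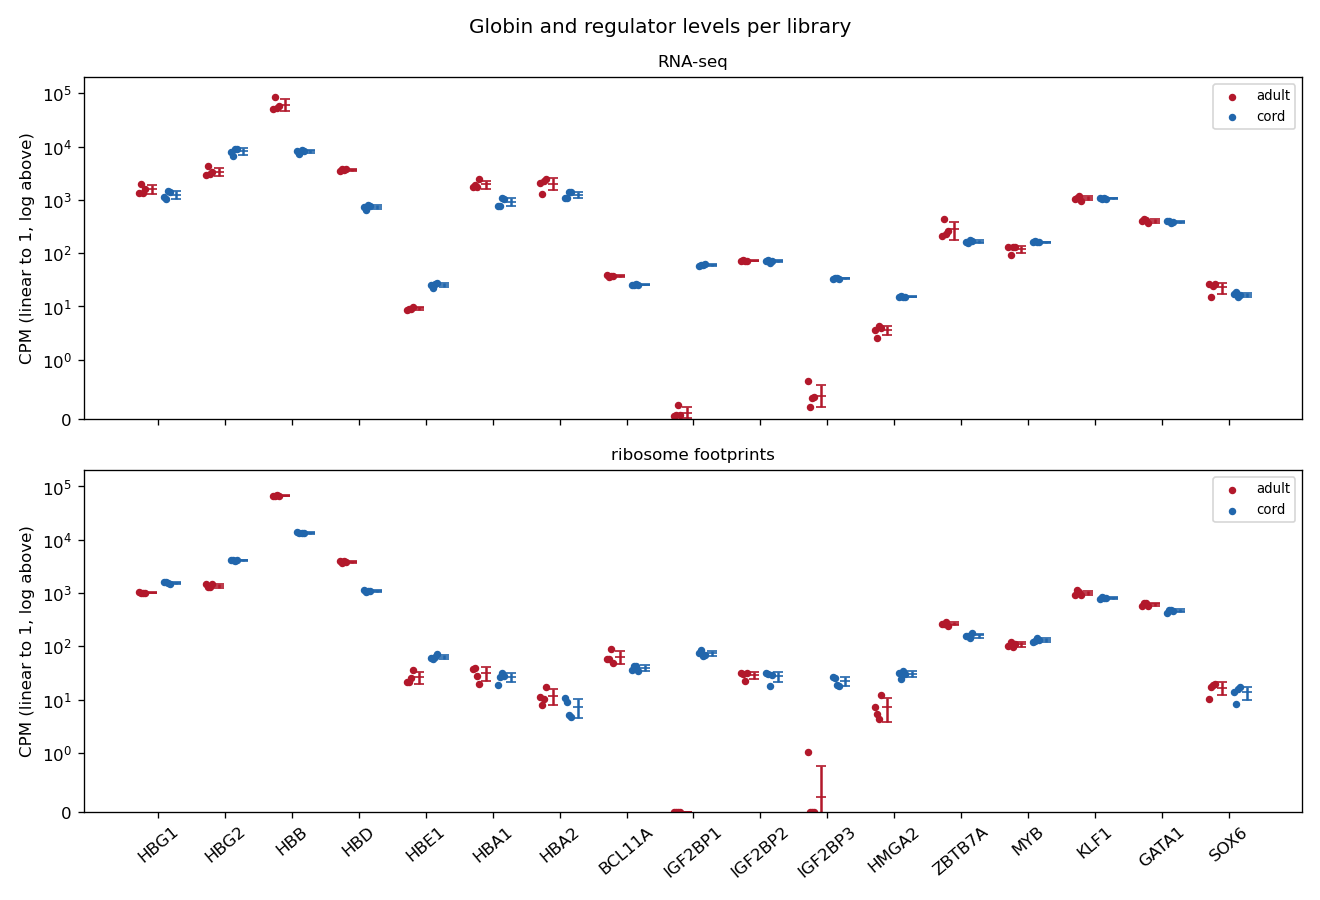
CPM of 17 key genes in every library, RNA and footprints, with adult in red and cord in blue, points for libraries and bars for mean ± SD (n = 4). The axis is linear up to 1 and logarithmic above it, and error bars stop at 0. HBB lies near 61410 CPM in adult and 8098 CPM in cord RNA, and IGF2BP1 near 0.107 and 60.1 CPM.

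In RNA, LIN28B, IGF2BP1, IGF2BP3 and granulocyte and monocyte markers were higher in cord cells, and heme synthesis and red cell membrane genes were lower. LIN28B, which blocks maturation of let-7 microRNAs, had 683 counts over the cord libraries (7.64 ± 0.799 CPM, SD, n = 4) and 0 over the adult ones, at least 240-fold higher against the floor of 3 counts over the group. The oncofetal RNA-binding proteins IGF2BP1 (60.1 ± 1.46 against 0.107 ± 0.093 CPM) and IGF2BP3 (33.6 ± 0.547 against 0.391 ± 0.189 CPM) and the chromatin protein HMGA2 (15.4 ± 0.45 against 3.65 ± 0.737 CPM) were higher in cord. IGF2BP2 did not pass the test (log2 -0.04 ± 0.0619, adjusted p = 0.649). BCL11A RNA was lower in cord, at 25.6 ± 0.608 against 37.7 ± 1.35 CPM (log2 -0.56 ± 0.0659, adjusted p = 0.000151).

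Across 13289 genes tested, 5214 passed, 2689 higher and 2525 lower in cord, with 774 higher and 575 lower by at least 1 on the log2 scale. The RNA library of adult replicate 2 stood apart on the second principal component, at -45.4 where the other adult libraries lay between 16.1 and 24. Without that replicate 8181 genes passed, 5203 of them among the 5214. Besides IGF2BP1, LIN28B and IGF2BP3, the genes of largest rise, among those of at least 5 CPM whose groups did not overlap, were WNT5B, a Wnt ligand (log2 7.27 ± 0.168), SLC10A4, a member of the bile acid transporter family (7.09 ± 0.151), and GABRE, a GABA receptor subunit (6.84 ± 0.424). All 5 adult counts of GABRE were in replicate 3, and its fitted change without that replicate was 10.21, against 0 adult counts, which is no bound. By the same limits, genes of largest fall were DES, the muscle intermediate filament desmin (-8.09 ± 0.397), NLRP2, an NLR family protein (-7.64 ± 0.208), MTRNR2L1, a copy of a mitochondrial rRNA segment (-6.79 ± 0.362, or -7.48 without cord replicate 1), and HSD11B2, which inactivates cortisol (-5.15 ± 0.278). PRR34-AS1 had 3 cord and 550 adult counts, a ratio of 174 (95% counting interval 59.3 to 848). It is annotated as an antisense RNA and whether counting used strand is not given in the sources used here. RNA28S5, an rRNA, was also lower (-5.18 ± 1.34), at 20.01 CPM in adult replicate 2 and 0.875 to 3.06 CPM in the other adult libraries, and its change without that replicate was -3.53.

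The regulators of globin switching showed no common direction, with 4 of 31 higher and 4 lower (the same numbers adjusted over the list alone, camera adjusted p = 0.985). Their median log2 was 0.00411 and their mean 0.252. Those higher were LIN28B, GATAD2A, CHD4 and MYB, and those lower NFIX, BCL11A, TAL1 and ZBTB7A. NFIX, a repressor of gamma-globin, changed by -1.20 ± 0.111 and TAL1, an erythroid transcription factor, by -0.45 ± 0.0657. MYB, a progenitor transcription factor, rose by 0.42 ± 0.106 (adjusted p = 0.012). ZBTB7A, the other main repressor of gamma-globin, changed by -0.77 ± 0.211 (adjusted p = 0.0168). Its call was lost without cord replicate 2 (0.0522), and its change was -0.48 without adult replicate 2. KLF1 (log2 -0.00, adjusted p = 0.977) and GATA1 (-0.07, 0.493), central erythroid factors, did not pass. SOX6 did not pass either (-0.45 ± 0.167, 0.057), but did without adult replicate 2 (-0.61, 9.46e-07) and with RLE size factors, DESeq2 or all 16 libraries in a single fit (0.0247 to 0.045). The last of these also called HBG1 (-0.36, 0.0182). The globin list had 3 of 10 members higher (HBZ, HBE1, HBG2) and 5 lower (HBD, HBB, HBA1, HBQ1, HBA2), the same numbers over the list alone, and its test did not pass (adjusted p = 0.157, median -0.517).

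The LIN28B and let-7 target list was higher in cord, with 18 of 33 members higher and 1, CDC34, lower (20 and 2 adjusted over the list alone, camera adjusted p = 6.49e-14, median log2 0.383, mean 1.43). ARID3A, a let-7 target and transcription factor, rose from 13.6 to 34.6 CPM (log2 1.35 ± 0.0705). Red cell maturation genes went the other way. Of 20 heme synthesis genes 13 were lower and 1, ALAS1, higher (14 and 1 over the list alone, adjusted p = 0.00027, median -0.42): CPOX fell from 891 to 381 CPM, and SLC25A37, the mitochondrial iron importer, from 1274 to 700 CPM. Of 24 membrane and skeleton genes 18 were lower and 1, ICAM4, higher (19 and 1 over the list alone, adjusted p = 1.41e-05, median -0.421). AQP1, the water channel, changed by -1.73 ± 0.0908 and BCAM by -1.92 ± 0.141. Of 24 late maturation genes 15 were lower and 1, SELENBP1, higher (15 and 2 over the list alone, adjusted p = 0.000738, median -0.436), including CA1, carbonic anhydrase 1 (-2.07 ± 0.2), and BNIP3L, a mitophagy receptor (-0.93 ± 0.113). With an estimated correlation the late maturation list had an adjusted p = 0.0717, and the LIN28B, heme and membrane lists kept their calls (0.00283, 0.0316 and 0.0316).

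Early progenitor genes were higher in cord, 8 of 16, with HOXA10 and SPINK2 lower (the same numbers over the list alone, adjusted p = 0.0367, median 0.31). GATA2, the progenitor GATA factor, rose by 1.34 ± 0.074, MYC by 0.67 ± 0.0721 and MECOM by 2.01 ± 0.197. Of 36 ribosome biogenesis genes 18 were higher and 1, UBTF, lower (19 and 1 over the list alone, adjusted p = 0.0208, median 0.293), such as NOP56 (0.51 ± 0.0633) and POLR1B (0.71 ± 0.104). Of 27 protein folding genes 16 were higher and 0 lower (18 and 0 over the list alone, adjusted p = 0.00823, median 0.29), such as HSPA8 (2756 against 1710 CPM) and the cochaperone BAG3 (1.49 ± 0.146). With an estimated correlation these 3 lists had adjusted p = 0.0972, 0.0717 and 0.259.

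Markers of other blood cells moved with these groups. Of 22 granulocyte and monocyte markers 20 were higher in cord and 1, CEBPA, lower (the same over the list alone, adjusted p = 1.18e-25, median 1.76, mean 2.21, adjusted p = 0.00485 with an estimated correlation). MPO, the neutrophil peroxidase, stood at 181 ± 4.01 against 36.9 ± 1.69 CPM (SD, n = 4), PRTN3 at 62.4 against 7.76 and ELANE at 59.0 against 16.7. Of 17 mast cell, basophil and eosinophil markers 8 were higher and 0 lower (9 and 1 over the list alone, adjusted p = 1.15e-05, median 0.408), with the eosinophil gene PRG3 up by 2.05 ± 0.0952. Of 11 macrophage markers 7 were higher and 1, CTSL, lower (7 and 2 over the list alone, adjusted p = 0.0259, median 0.485), with APOE at 322 against 101 CPM. Of 6 lymphoid markers 5 were higher (CD74, NKG7, IL7R, CD79B and LTB, the same over the list alone, adjusted p = 1.41e-05, median 1.84). Megakaryocyte markers were lower, 7 of 17, with THBS1 and GP9 higher (the same over the list alone, adjusted p = 0.0159, median -0.337), led by VWF (-2.49 ± 0.119). With an estimated correlation these last 4 lists had adjusted p = 0.0717, 0.0972, 0.0717 and 0.0823.

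The other RNA lists did not pass. Iron handling had 2 of 20 members higher, HMOX2 and NFS1, and 7 lower (3 and 7 over the list alone, adjusted p = 0.738, median -0.0111), and erythroid transcription factors 2 of 20 higher, MYB and KIT, and 8 lower (2 and 9 over the list alone, adjusted p = 0.0715, median -0.152). Glycolysis had 4 of 27 higher, among them PKM, TKT and ENO1, and 13 lower (the same over the list alone, adjusted p = 0.0679, median -0.295): PKM rose by 1.29 ± 0.101 where PFKM changed by -1.07 ± 0.0831. Cell cycle had 2 of 41 higher, AURKB and TYMS, and 11 lower (1 and 9 over the list alone, adjusted p = 0.0639, median -0.139), including CDKN2C, a cyclin-dependent kinase inhibitor (-1.13 ± 0.158). Glycolysis and cell cycle passed without adult replicate 2 (0.0328 and 0.00165) and without adult replicate 4 (0.0202 and 0.035). The mitochondrial ribosome list passed without adult replicate 2 (0.0224) and the erythroid transcription factors without adult replicate 4 (0.0301). The mitochondrial ribosome had 17 of 77 higher and 1, MRPS10, lower (13 and 1 over the list alone, adjusted p = 0.164, median 0.118). Cytosolic ribosomal proteins had 5 of 85 higher (RPL39L, RPS10, RPL7L1, RPL26L1 and RPL29) and 20 lower (3 and 17 over the list alone, adjusted p = 0.169, median -0.0546). The TOP list, of translation factors and some other genes, had 1 of 24 higher, VIM, and 3 lower, NAP1L1, TPT1 and PABPC1 (1 and 2 over the list alone, adjusted p = 0.936, median 0.0802 and mean 0.0189, with the test pointing down). The PABPC1 call (adjusted p = 0.0267) was lost without adult replicate 1 or 4 or any single cord replicate (0.0552 to 0.087). Oxidative phosphorylation had 12 of 80 higher and 9 lower (9 and 7 over the list alone, adjusted p = 0.776, median 0.0294 and mean -0.0214, with the test pointing down).

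Among the remaining RNA lists, the stress response list had 6 of 26 higher, with TRIB3 at 1.49 ± 0.158, and 5 lower, VLDLR, PPP1R15A, DDIT4, CEBPG and SESN2 (the same over the list alone, adjusted p = 0.985, median -0.00331 and mean 0.0104, with the test pointing up). The proteasome had 9 of 35 higher and 2 lower, UBE2H and PSMD12 (9 and 1 over the list alone, adjusted p = 0.169, median 0.214), interferon response 6 of 33 higher and 12 lower (6 and 13 over the list alone, adjusted p = 0.164, median -0.263), cholesterol synthesis 3 of 30 higher, among them DHCR7, and 11 lower (3 and 12 over the list alone, adjusted p = 0.218, median -0.208) and replication-dependent histones 9 of 43 higher and 0 lower (6 and 0 over the list alone, adjusted p = 0.218, median 0.317). In the interferon list IFITM3 was at 71.4 against 1.67 CPM and IFI27 at 10.1 against 42.9 CPM.

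In footprints, IGF2BP1, IGF2BP3 and HMGA2 were higher in cord, and heme synthesis, membrane, late maturation and histone genes were lower. IGF2BP1 had 778 deposited footprint counts over the cord libraries (73.9 ± 8.93 CPM, SD, n = 4) and 0 over the adult ones, at least 78.5-fold higher against the floor of 3 reads, or 6 deposited counts. LIN28B had 60 cord and 0 adult counts and was below the filter for low counts, so it was not tested. HMGA2 was at 30.2 against 7.38 CPM, and IGF2BP3 had 119 cord and 1 adult reads, a ratio of 72.4 (95% counting interval 12.7 to 2880), the adult read being in replicate 1. BCL11A footprints were lower in cord, at 39.5 ± 4.78 against 64.3 ± 18.3 CPM (log2 -0.69 ± 0.168, adjusted p = 0.00338). ZBTB7A (-0.72 ± 0.0866), KLF1 (-0.32 ± 0.071) and GATA1 (-0.40 ± 0.0738) were also lower, while MYB (0.25, adjusted p = 0.0819), SOX6 (-0.26, 0.567) and IGF2BP2 (-0.06, 0.88) did not pass.

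Of 9760 genes tested in footprints 2113 passed, 970 higher and 1143 lower, with 238 higher and 295 lower by at least 1 on the log2 scale. The footprint library of adult replicate 3 stood apart on the second principal component, at -34.3 where the other adult libraries lay between 11 and 15.4. Without that replicate 2097 genes passed, 1826 of them among the 2113. COL4A5, a basement membrane collagen, had 172 cord and 0 adult counts, at least 17.2-fold higher, and PRR34-AS1 had 0 cord and 44 adult counts, at least 12.2-fold lower. SLC10A4 had 209 cord and 1 adult reads (ratio 127, counting interval 22.6 to 5040) and HPGDS, a prostaglandin D synthase of mast cells, 133 and 3 (27, 9.03 to 132). NLRP2 had 1 cord and 77 adult reads (127, 22.1 to 5070), HSD11B2 1 and 54 (88.8, 15.3 to 3570), DES 1 and 46 (75.6, 12.9 to 3050) and SPATA4 1 and 30 (49.3, 8.2 to 2010). The single read was in adult replicate 3 for SLC10A4, in cord replicate 1 for NLRP2 and DES and in cord replicate 2 for HSD11B2 and SPATA4, without which those groups were at 0. MTRNR2L1 changed by -5.77 ± 0.346.

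The footprint list of LIN28B and let-7 targets had 12 of 24 members higher and 1, CDC34, lower (14 and 1 over the list alone, camera adjusted p = 1.14e-07, median 0.421, mean 1.11), with ARID3A at 40.3 against 15.5 CPM. Of 20 heme synthesis genes 16 were lower and 0 higher (16 and 1 over the list alone, adjusted p = 1.28e-12, median -0.526), among them CPOX (664 against 1247 CPM) and GLRX5, an iron-sulfur protein (-0.75 ± 0.0747). Of 24 membrane and skeleton genes 17 were lower, and ICAM4 and TPM3 were higher (20 and 2 over the list alone, adjusted p = 1.14e-11, median -0.488). SLC4A1, the anion exchanger band 3, stood at 1454 against 2450 CPM. Late maturation genes were lower in 13 of 24 cases and higher in 0 (15 and 2 over the list alone, adjusted p = 2.81e-13, median -0.512), with CA1 at -2.29 ± 0.121 and CA2 at -1.37 ± 0.081. Of 20 erythroid transcription factors 11 were lower, and KIT and STAT5A were higher (11 and 3 over the list alone, adjusted p = 0.00141, median -0.326). GFI1B, a repressor needed for erythroid and megakaryocytic cells, was at 379 against 618 CPM. Of 26 glycolysis genes 15 were lower, and PKM and LDHB were higher (15 and 5 over the list alone, adjusted p = 4.64e-05, median -0.277). Early progenitor genes were higher in 5 of 7 cases (GATA2, KIT, MYC, LMO4 and CD44, the same over the list alone, adjusted p = 0.00133, median 0.484). The LMO4 call was lost without adult replicate 1 (0.065) or cord replicate 3 (0.0678). These 7 lists kept their calls with an estimated correlation (0.00395 to 0.0345).

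The ribosome biogenesis, protein folding and mitochondrial ribosome lists were higher in cord footprints. Ribosome biogenesis had 22 of 36 members higher and 1, UBTF, lower (25 and 1 over the list alone, adjusted p = 1.8e-07, median 0.373), with the RNA helicase DDX21 at 0.73 ± 0.092. Protein folding had 19 of 27 higher and 0 lower (21 and 0 over the list alone, adjusted p = 9.39e-10, median 0.401), with HSPA8 at 1166 against 689 CPM. The mitochondrial ribosome had 17 of 77 higher and 1, MRPL2, lower (18 and 1 over the list alone, adjusted p = 0.00234, median 0.158). The proteasome had 15 of 35 higher and 0 lower (17 and 1 over the list alone, adjusted p = 0.000219, median 0.212), with adjusted p = 0.103 with an estimated correlation. Cytosolic ribosomal proteins had 11 of 76 higher and 1, RPL14, lower (10 and 1 over the list alone, adjusted p = 0.0406, median 0.0883). With an estimated correlation their adjusted p was 0.0899, and the call was lost without adult replicate 4 (0.0552) or cord replicate 3 (0.0509).

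Replication-dependent histones went the other way, with 43 of 56 lower in cord footprints and 1, HIST1H3E, higher (45 and 1 over the list alone, adjusted p = 4.39e-13, median -0.365). HIST1H2AG, for example, stood at 3297 against 4989 CPM. Small noncoding RNAs, with rRNA, moved with them, at 5.15% ± 0.433 (SD, n = 4) of cord and 6.696% ± 0.147 of adult footprint counts, while protein-coding genes took 93.66% ± 0.453 and 91.91% ± 0.159. Neither share overlapped between the groups (exact permutation p = 0.0286 for both, 0.0352 adjusted over the 16 shares). In RNA these shares did not pass (exact permutation p = 0.8 and 1). Cell cycle genes were lower in 11 of 41 cases, with AURKA and BUB1 higher (13 and 2 over the list alone, adjusted p = 0.0386, median -0.081). Their call was lost without adult replicate 1 (0.0542), adult replicate 4 (0.0575) or cord replicate 2 (0.0717), and the adjusted p was 0.0973 with an estimated correlation. CDKN2C was lower by the most of those named (-1.44 ± 0.147). In cholesterol synthesis 5 of 29 were lower (FADS2, SREBF1, SREBF2, INSIG1 and DHCR7) and 0 higher (the same over the list alone, adjusted p = 0.031, median -0.123), with adjusted p = 0.103 with an estimated correlation.

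Granulocyte and monocyte markers were higher in cord footprints in 7 of 12 cases, with CEBPA lower (9 and 1 over the list alone, adjusted p = 9.39e-10, median 1.1). MPO was at 232 against 65.3 CPM, and LYZ, lysozyme, rose by 1.95 ± 0.205. Mast cell, basophil and eosinophil markers were higher in 6 of 14 cases, with RNASE2 lower (7 and 1 over the list alone, adjusted p = 0.00158, median 0.398). Megakaryocyte markers were lower in 6 of 13 cases and higher in 0 (the same over the list alone, adjusted p = 0.000304, median -0.622), with VWF at -2.85 ± 0.278 and adjusted p = 0.0503 with an estimated correlation. Macrophage markers did not pass (adjusted p = 0.051, median -0.17 and mean 0.232, with the test pointing up). APOE and APOC1 were higher, and CTSB and CTSD lower, the same numbers over the list alone. The macrophage list passed without adult replicate 2 (0.0281) or 3 (0.0284) and without cord replicate 4 (0.0449). The CTSD call (adjusted p = 0.0447) was lost without any single replicate except adult replicate 1 (0.0647 to 0.114), with no filter for low counts (0.0977) and with all 16 libraries in a single fit (0.12). With 3 members measured, the lymphoid list was not tested. CD74 and NKG7 were higher, the latter lost without cord replicate 2 (0.076).

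The other footprint lists did not pass. Globins had 4 of 10 higher (HBG2, HBZ, HBG1 and HBE1) and 4 lower (HBB, HBD, HBQ1 and HBM, the same over the list alone, adjusted p = 0.336, median -0.344 and mean 0.03, with the test pointing down). Regulators of switching had 2 of 30 higher, CHD4 and HIC2, and 8 lower (3 and 8 over the list alone, adjusted p = 0.249, median 0.025 and mean -0.087, with the test pointing down). NFIA, a factor of the NFI family, stood at 101 against 175 CPM. Iron handling had 2 of 20 higher, HMOX2 and FTL, and 7 lower (the same over the list alone, adjusted p = 0.249, median -0.148). The TOP list had 5 of 24 higher, EIF3M, EIF3E, EIF3D, VIM and NPM1, and 0 lower (the same over the list alone, adjusted p = 0.0633, median 0.141), and passed without adult replicate 1 (0.0401). The EIF3E call was lost with all 16 libraries in a single fit (0.0572). The stress response had 4 of 25 higher, HSPA5, TRIB3, XBP1 and MTHFD2, and 3 lower, DDIT4, PPP1R15A and SESN2 (the same over the list alone, adjusted p = 0.458, median 0.12). Interferon response had 2 of 24 higher, IFITM3 and OAS3, and 5 lower, IFI27, IRF9, EPSTI1, TAP1 and IFITM2 (the same over the list alone, adjusted p = 0.431, median -0.0702), and oxidative phosphorylation 2 of 76 higher, ATP5G3 and ATP5B, and 8 lower (1 and 3 over the list alone, adjusted p = 0.846, median -0.03).

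RNA and footprint changes went together across genes. Of 9607 genes tested in both assays, 627 were higher in both, where 179 would be shared by independent lists of 1777 and 966 genes. A further 738 were lower in both, where 206 would be shared by lists of 1846 and 1074, and 32 were called in opposite directions. Across these genes, which are not independent replicates, the log2 changes had Pearson r = 0.775 and Spearman rho = 0.639, with a covariance of 0.23. In 18 splits of the samples that mixed both origins equally, r lay between -0.101 and 0.211 and the covariance reached 0.00751.

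**Figure D2:**
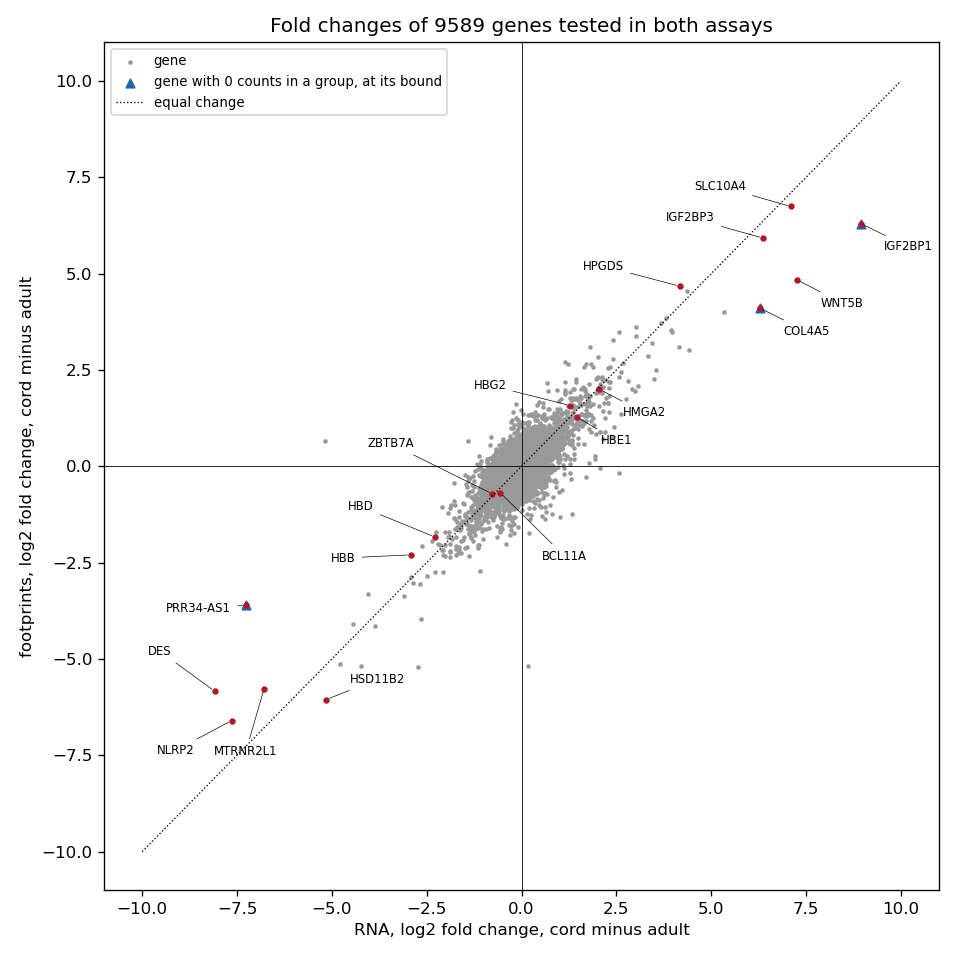
Log2 change of footprints (vertical axis) against log2 change of RNA (horizontal axis), cord minus adult, for 9589 genes, each gene a point, with the dotted line at equal change. Red labelled points are the genes of largest footprint change, among those of at least 5 CPM whose groups did not overlap, and the key genes called in both assays, and 3 triangles stand at lower bounds because a group had 0 counts. The cloud follows the line (r = 0.775 over the 9607 genes tested in both assays).

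Translational efficiency, the footprint level relative to RNA, differed between origins for few genes. BCL11A showed no detectable difference: its log2 ratio of footprints to RNA was 0.74 ± 0.176 (SD, n = 4) in cord and 0.82 ± 0.356 in adult samples. The difference was -0.08 ± 0.204 (SE, 95% interval -0.581 to 0.419, edgeR adjusted p = 0.941), with 412 cord and 402 adult footprint counts behind it. It was 0.10 without adult replicate 3 (adjusted p = 0.892), whose footprint library stood apart from the other adult ones. HBG1 had more footprints per RNA in cord (log2 0.99 ± 0.156, interval 0.614 to 1.38, adjusted p = 0.00246), as did HBB (0.63 ± 0.139, 0.0432). How reads of the near-identical HBG1 and HBG2 were divided or left uncounted in each assay is uncertain, so the HBG1 value is too. The HBB call was lost without adult replicate 4 (0.122) or any single cord replicate (0.175 to 0.274), with RLE size factors (0.0703), with DESeq2 (0.0553) and with no replicate block (0.0778). For LIN28B, IGF2BP1 and IGF2BP3 no efficiency was estimable, since adult counts were near 0.

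HBG2 (log2 0.33, interval -0.0304 to 0.697, adjusted p = 0.389), HBD (0.50, 0.0704), HBA1 (0.86, 0.115), KLF1 (-0.28, 0.35) and GATA1 (-0.29, 0.346) did not pass. HBE1 (-0.15), HBA2 (0.10), IGF2BP2 (0.01), HMGA2 (-0.01), ZBTB7A (0.02), MYB (-0.13) and SOX6 (0.20) did not pass either (0.826 to 1). HBD passed without adult replicate 2 (0.00225), HBA1 without adult replicate 1 (0.0415) or 2 (0.0025), and KLF1 with DESeq2 (0.0456). HBD also passed with DESeq2 (0.00922), with no replicate block (0.0405), with footprint counts divided by 2 (0.0342) and with no filter for low counts (0.00578), and HBA1 with the last of these (0.000166). HMGA2 was 0.29 without adult replicate 4.

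Of 13628 genes tested for efficiency, 60 passed, 16 higher and 44 lower in cord, 5 and 26 of them by at least 1 on the log2 scale. An unadjusted p under 0.05 was reached by 1544 genes, and DESeq2 called 173. The count was 305 without adult replicate 2 (156 higher, 149 lower) and 17 without cord replicate 1, 34 without cord replicate 2, 30 without cord replicate 3, 29 without cord replicate 4 and 29 without adult replicate 4. With RLE size factors 73 passed, 16.4% of them higher where the main share was 26.7%. With no filter for low counts 254 did, 145 higher, and with footprint counts divided by 2 there were 104, 36 higher.

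Among genes of at least 5 CPM in RNA whose ratios did not overlap between groups, those of largest rise in efficiency were MPHOSPH6, an exosome cofactor (log2 1.53 ± 0.275), UBXN2A (1.18 ± 0.238), SNRNP25, a minor spliceosome protein (1.16 ± 0.169), GINS1, a replication factor (1.003 ± 0.201), HBG1 and RPSA (0.99 ± 0.186). Those of largest fall included GDF11, a TGF-beta family ligand (-2.08 ± 0.312), MEX3D (-1.88 ± 0.228), MEF2C, a transcription factor (-1.80 ± 0.313), FNBP1 (-1.77 ± 0.347) and IFITM2 (-1.72 ± 0.268). MPHOSPH6 and MEF2C lost their calls without cord replicate 1 (0.0673 for both). UBXN2A and GINS1 lost theirs without adult replicate 4 (0.103 and 0.0781), cord replicate 1 (0.15 and 0.171), 2 (0.121 and 0.0787) or 3 (0.087 and 0.0725), and GINS1 also without cord replicate 4 (0.0811). RPSA lost its call without cord replicate 1 (0.0882), 2 (0.0743) or 3 (0.087), and RPSA and GINS1 did with no replicate block (0.105 and 0.0795). FNBP1 lost its call without adult replicate 4 (0.116), cord replicate 1 (0.146), 3 (0.0936) or 4 (0.0811). GDF11, MEX3D, IFITM2, SNRNP25 and HBG1 kept theirs without any single replicate.

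By group, replication-dependent histones were lower in efficiency in cord, 8 of 57 with 0 higher (27 and 1 adjusted over the list alone, camera adjusted p = 2.75e-18, median -0.63). HIST1H1C changed by -1.07 ± 0.126, HIST1H3H by -1.12 ± 0.164 and HIST1H2BK by -0.98 ± 0.151. Histones took 0.01594% of cord and 0.01301% of adult RNA counts, against 6.327% and 7.354% of footprint counts. How much histone RNA the RNA libraries captured is not known, so these ratios may not measure translation. The footprint share of small noncoding RNAs with rRNA was also lower in cord (5.15% against 6.696%). Cytosolic ribosomal proteins were higher, 6 of 85 with 0 lower (20 and 2 over the list alone, adjusted p = 4.18e-06, median 0.221, or 0.234 without genes that had 0 footprints in a group). RPS14 rose by 0.78 ± 0.126, RPL37A by 0.78 ± 0.134 and RPL23 by 0.68 ± 0.12, the last 2 calls lost without cord replicate 1 (0.0614 for RPL37A, 0.0858 for RPL23). Both lists kept their calls with an estimated correlation (0.00417 and 0.0282). The TOP genes (0 called, 4 higher over the list alone, adjusted p = 0.00351, median 0.144) and protein folding (0 called, 1 lower over the list alone, adjusted p = 0.00615, median 0.139) were higher as lists. Megakaryocyte markers were lower as a list (adjusted p = 0.00615, median -0.253, or -0.229 without genes at 0), where THBS1, a platelet adhesion protein, was the called gene (-0.94 ± 0.119, the same count over the list alone). With an estimated correlation these 3 had adjusted p = 0.275, 0.405 and 0.115. Protein folding was also lost without adult replicate 3 (0.0715) and with no replicate block (0.0632).

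The other 22 efficiency lists did not pass. Globins had HBG1 and HBB higher (4 and 1 over the list alone, adjusted p = 0.085, median 0.405), and passed with no replicate block (0.00879) and without adult replicate 4 (0.0441). In the erythroid transcription factors GFI1B was lower (-0.65 ± 0.134, adjusted p = 0.0251, list adjusted p = 0.181, median 0.00335 and mean -0.0486, with the test pointing down). Its call was lost without any single replicate but adult 2 or 3 (0.0618 to 0.198) and with no replicate block (0.0686). THBS1 was lower in the LIN28B and let-7 list (list adjusted p = 0.733, median 0.0976, or 0.0961 without genes at 0) and IFITM2 in interferon response (adjusted p = 0.52, median 0.111 and mean -0.111, with the test pointing down). Cholesterol synthesis had 0 members higher and 1 lower (0 and 2 over the list alone, adjusted p = 0.942, median 0.0584 and mean -0.0537, pointing down). No member was called in late maturation (adjusted p = 0.085, median -0.0628), glycolysis (adjusted p = 0.085, median -0.0728), granulocyte and monocyte markers (adjusted p = 0.085, median 0.0264, mean 0.406, pointing down, -0.165 without genes at 0, 0 and 4 over the list alone) or mast cell markers (adjusted p = 0.085, median -0.213, or -0.18 without genes at 0). None was called either in early progenitor (adjusted p = 0.113, median -0.178, or -0.0653 without genes at 0), biogenesis (adjusted p = 0.157, median 0.141), heme (adjusted p = 0.585, median -0.0249, mean 0.0175, pointing down), iron (adjusted p = 0.55, median 0.0405, mean -0.00793, pointing down), membrane (adjusted p = 0.593, median -0.0194) or regulators of switching (adjusted p = 0.755, median 0.0687, or 0.0792 without genes at 0). Nor was any in the stress response (adjusted p = 0.733, median 0.0665), proteasome (adjusted p = 0.523, median 0.036), cell cycle (adjusted p = 0.52, median 0.0948), mitochondrial ribosome (adjusted p = 0.552, median 0.0611), oxidative phosphorylation (adjusted p = 0.755, median -0.0157, or 0.00908 without genes at 0, 5 and 2 over the list alone), macrophage (adjusted p = 0.552, median -0.202, or -0.262 without genes at 0) or lymphoid lists (adjusted p = 0.915, median -0.113, mean 1.34, pointing down, -0.378 without genes at 0). Adjusted over the list alone, numbers were as over all genes except where given. Without adult replicate 2, glycolysis (0.038), proteasome (0.0343) and granulocyte and monocyte markers (0.027) passed, and without adult replicate 3, late maturation (0.0305) and mast cell markers (0.0365). With RLE size factors late maturation (0.0387) and glycolysis (0.0172) did.

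Averaged over both origins, footprints and RNA of the same samples differed widely between genes. Histone messages had far more footprints than RNA reads: HIST1H1B stood at 2.43 CPM in RNA and 4864 CPM in footprints (log2 10.95 ± 0.0925, SE), and HIST1H3G and HIST1H2AH were similar (11.18 ± 0.0987 and 10.89 ± 0.101). Messages of ferritin, alpha-globin and elongation factor 1 had far fewer: FTH1 and FTL, the ferritin chains, changed by -4.98 ± 0.069 and -5.09 ± 0.0777, HBA1 by -5.43 ± 0.117, HBA2 by -7.27 ± 0.13 and EEF1A1 by -7.89 ± 0.131. BCL11A had more footprints than RNA (0.79 ± 0.103, adjusted p = 9.83e-07), as did TFRC, the transferrin receptor (0.91 ± 0.0682).

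Of 13628 genes tested, 8321 passed, 3545 with more and 4776 with fewer footprints. Among genes of at least 5 CPM in RNA, the largest excess was at ZNF773, a zinc finger gene with 25970 CPM in footprints and 8.12 CPM in RNA (11.66 ± 0.0977). It was followed by the untranslated RNAs RN7SL2, of the signal recognition particle (9.21 ± 0.213), and RPPH1, of RNase P (8.14 ± 0.163), the histones HIST1H1C (8.12 ± 0.0809) and HIST1H2AC (8.08 ± 0.0818) and RMRP, of RNase MRP (6.70 ± 0.135). RPS28 had 617 CPM in RNA and 0 footprints, at least 1670-fold lower against the floor of 3 reads over the 8 footprint libraries. RPL39 (at least 90.4-fold), SLMO2 (72.5), H3F3AP4 (71.2), ISY1 (58.1) and NPIPB3 (50.2) also had 0 footprints. RPS28, RPL39, H3F3AP4, NPIPB3 and the histones, ferritins and EEF1A1 have near-identical copies or pseudogenes, so their counts are uncertain. Whether the footprint reads counted for ZNF773 came from its message is also uncertain. It is likewise not known whether the 0 footprints of SLMO2 and ISY1 reflect translation or the counting. Strand use and the treatment of reads that fit several genes are not given in the sources used here. Among key genes, HBB (0.55 ± 0.0697), HBD (0.43 ± 0.059), HBE1 (1.51 ± 0.11), HMGA2 (1.10 ± 0.183) and GATA1 (0.54 ± 0.0598) had more footprints, and HBG2 (-1.03 ± 0.075), IGF2BP2 (-1.25 ± 0.101) and KLF1 (-0.15 ± 0.0577, adjusted p = 0.0296) fewer. The KLF1 call was lost without adult replicate 1, 3 or 4 or cord replicate 1, 3 or 4 (0.0571 to 0.135), with RLE size factors (0.207), DESeq2 (0.111) or no replicate block (0.0722). HBG1 (-0.03, 0.733), ZBTB7A (0.07, 0.536), MYB (-0.12, 0.218) and SOX6 (-0.26, 0.178) did not pass, although the last 3 did without adult replicate 2 (0.00239, 0.00671 and 0.0451). HBG1 was 0.04 without adult replicate 2.

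By group, all 57 histones had more footprints than RNA (the same over the list alone, camera adjusted p = 3.7e-64, median 10). Of 85 cytosolic ribosomal proteins 69 had fewer and 6 more (70 and 6 over the list alone, adjusted p = 2.78e-18, median -1.51), such as RPL13A (-4.30 ± 0.0729) and RPS26 (-9.05 ± 0.19). Of 24 members of the TOP list 18 had fewer and EIF3K, GNB2L1, EIF3E and EIF3D more (the same over the list alone, adjusted p = 1.15e-05, median -1.25), with EIF4B at -3.69 ± 0.0821. More footprints than RNA were found for 39 of 77 mitochondrial ribosome genes, with 15 fewer (41 and 15 over the list alone, adjusted p = 0.00153, median 0.225), 23 of 35 proteasome genes, with 7 fewer (the same over the list alone, adjusted p = 0.000862, median 0.344), and 23 of 41 cell cycle genes, with 6 fewer (24 and 6 over the list alone, adjusted p = 0.00164, median 0.269), such as MCM5 (1.29 ± 0.0593). The same held for 39 of 81 oxidative phosphorylation genes, with 19 fewer (the same over the list alone, adjusted p = 0.0124, median 0.157), 11 of 17 megakaryocyte markers, with 0 fewer (the same over the list alone, adjusted p = 0.0127, median 0.565), and 9 of 21 granulocyte and monocyte markers, with CSF3R fewer (the same over the list alone, adjusted p = 0.0482, median 0.394). With an estimated correlation the histones (0.0293), ribosomal proteins (0.00298) and mitochondrial ribosome (0.0293) kept their calls. The TOP, proteasome, cell cycle, oxidative phosphorylation, megakaryocyte and granulocyte lists then had adjusted p = 0.0849, 0.225, 0.131, 0.225, 0.111 and 0.237. Granulocyte and monocyte markers lost their call without adult replicate 1 (0.0689), 3 (0.0545) or 4 (0.0857) or cord replicate 2 (0.0501) or 3 (0.0577), and with RLE size factors (0.0615). With no replicate block the proteasome (0.075), cell cycle (0.11), mitochondrial ribosome (0.0798), oxidative phosphorylation (0.394), megakaryocyte (0.124) and granulocyte (0.41) calls were lost.

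The other within-sample lists did not pass, and their numbers adjusted over the list alone were as over all genes except where given. Genes with more and with fewer footprints numbered 10 and 6 in heme synthesis (adjusted p = 0.263, median 0.258), 10 and 5 in iron handling (FTH1, FTL, STEAP3, SLC40A1 and ISCU fewer, adjusted p = 0.358, median 0.276, mean -0.295, pointing up) and 7 and 10 in membrane genes (adjusted p = 0.927, median -0.124). They numbered 4 (AHSP, EPB42, CA2 and UBE2O) and 13 in late maturation (adjusted p = 0.363, median -0.226), 6 and 9 in erythroid transcription factors (adjusted p = 0.912, median -0.134) and 12 and 13 in regulators of switching (adjusted p = 0.912, median -0.118, with the test pointing up). In globins they were 3 (HBE1, HBB and HBD) and 4 (HBA2, HBA1, HBG2 and HBQ1, adjusted p = 0.694, median -0.0995), in the LIN28B and let-7 list 8 and 11 (adjusted p = 0.8, median -0.162), in early progenitor genes 6 and 3 (BCL2, GATA2 and ETV6, adjusted p = 0.261, median 0.112) and in glycolysis 13 and 9 (13 and 10 over the list alone, adjusted p = 0.395, median 0.0393, mean -0.142, pointing up). In ribosome biogenesis they were 15 and 5 (NCL, DKC1, RRN3, UBTF and NOP58, adjusted p = 0.101, median 0.106), in the stress response 11 and 10 (adjusted p = 0.709, median 0.136, mean -0.166, pointing up), in protein folding 13 and 9 (14 and 9 over the list alone, adjusted p = 0.321, median 0.139, mean -0.0455, pointing up) and in interferon response 10 and 2 (IFITM2 and SAMD9L, 9 and 1 over the list alone, adjusted p = 0.134, median 0.124). In cholesterol synthesis they were 13 and 8 (adjusted p = 0.321, median -0.00594, mean 0.0618, pointing up), in mast cell markers 7 and 4 (TPSB2, HDC, GATA2 and MS4A2, adjusted p = 0.263, median 0.238, mean -0.0347, pointing up), in macrophage markers 6 and 0 (adjusted p = 0.0932, median 0.604) and in lymphoid markers 3 (CD74, NKG7 and PRF1) and 1 (IGLL1, adjusted p = 0.476, median 0.155). The PRF1 call (adjusted p = 0.0242) was lost without cord replicate 1 (0.0729), 2 (0.0663) or 3 (0.0518), and with no filter for low counts (0.129).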

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

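The tests of the footprint slope of adult replicate 2 and of the histone messages against untranslated RNAs were chosen after the results were seen. Further readings, of the polyadenylated histone variants and of the near-identical copies, were left undecided only after their values were seen, because each value lay within its spread of the bound set for it.

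Of 94 groups of 4 libraries examined, 6 had a library far from the others, with a gap to its nearest neighbour that exceeded Dixon's 95% critical share of the range, where chance gives about 1 in 20. IGF2BP2 footprints were 22.1 CPM in adult replicate 3 and 29.8 to 31.1 in the other adult libraries. Globins took 2.34% of footprints in cord replicate 1 and 2.21% to 2.22% in the others. HMGA2 RNA was 16 CPM in cord replicate 2 and 15.1 to 15.2 in the others. The other 3 were in the RNA library of adult replicate 2, with histones at 0.0111% of counts (0.0134% to 0.0138% in the others), MYB at 94 CPM (129 to 130) and SOX6 at 14.8 CPM (24.2 to 26). Among 124 named genes, 16 had such a library in adult RNA, 13 of them adult replicate 2, against 4, 8 and 12 in cord RNA, adult footprints and cord footprints. The first comparison used CPM of total counts and was replaced by normalised CPM after its result had been seen. It found 8 of 95 groups, without IGF2BP2 and with HBG2 in cord footprints (4210 CPM in replicate 3, 4350 to 4370 in the others), HBA1 in adult RNA (2390 in replicate 4, 1680 to 1710) and MYB in cord RNA (176 in replicate 2, 166 to 168).

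The RNA library of adult replicate 2 stood apart from the other adult RNA libraries, with chi-square per gene of 87.2 to 115 in its pairs and 4.89 to 16.9 in the others. Lower depth is argued against, since after thinning to equal totals the ratio of these values was still 12.4 (94.9 against 7.64). Globins taking more of the counts are argued against, since without them this library deviated 2.33 times as far as the others (0.445 against 0.191). A difference between the cells could be carried into the footprints, if both libraries came from the same cells. The slope of footprint on RNA deviation over 1000 genes was 0.0112 (95% interval -0.0128 to 0.0347). The pairing comes from the series design text. Deviations of the other samples' 2 libraries also correlated weakly (-0.102 to 0.262), so the slope does not decide this. Handling of that RNA library may account for the pattern and was not tested.

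Histone messages had far more footprints than RNA, with a median log2 ratio of 10 over 57 genes (4.49 to 12). RNA libraries depleted of RNAs without a poly(A) tail could give this, and 7 polyadenylated histone variants had a median of -0.239 (-0.871 to 3.67), as that needs. Untranslated RNAs without a tail, however, had a median of 2.93 over 169 genes (-8.17 to 15.9), short of the 3 set for them. The histone median lay 7.1 above theirs, which more ribosomes on histone messages could also give, within the spread of those RNAs. The 2 explanations cannot be told apart, because the library protocol is not given in the sources used here.

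HBA1 and HBA2 had far fewer footprints than RNA (log2 -5.43 and -7.27). Short footprint reads shared by near-identical copies may have been left uncounted, and 12 other near-identical genes had a median log2 ratio of -0.579 (95% interval -1 to -0.0255), with 1, CBWD1 at -3.51, below -2. That interval reaches the bound of -1 set for excluding the explanation, so it stays open, as do differences in read length between the assays, which were not tested. No biological explanation was tested for these patterns beyond those named.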

How the results depend on the processing

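Footprint counts divided by 2 and protein-coding genes alone were chosen after seeing the data, and the causes of the changes below were not tested. Of the counts and shares under alternatives, 128 stayed within 1.5 times or kept their call, 8 were larger and 10 smaller. Leaving out a replicate gave 4025 to 8181 genes in RNA, 1708 to 2097 in footprints, 17 to 305 in efficiency and 7727 to 8573 within samples, and 5 to 8 lists in efficiency. For efficiency, 254 genes passed with no filter for low counts, 173 with DESeq2 (58 of the 60 among them) and 104 with footprint counts divided by 2. Lists called with an estimated correlation were 4 in RNA, 2 in efficiency and 3 within samples, and with fry 22, 3 and 24.

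No pairing of adult and cord samples by replicate number was seen. Deviations of same-numbered libraries correlated from -0.23 to 0.0275 in RNA and from -0.0388 to 0.0467 in footprints. The check cannot exclude a pairing, since the 2 libraries of a cord sample, paired by the series design text, correlated as weakly (-0.00891 to 0.0529). With the number as a replicate block 4095 genes passed in RNA, 2064 in footprints, and with the number crossed with assay 47 in efficiency. The block called the TOP list and macrophage markers in footprints (0.0491 for both) and did not call PABPC1 in RNA (0.0866) or CTSD in footprints (0.0504), and the crossed block did not call HBB (0.0586) or GFI1B (0.0699) in efficiency. These blocks changed no other call of a named gene, nor of a list in RNA or footprints, and lists were not tested with the crossed block. With no replicate block 59 passed in efficiency (43 shared), and 3 lists within samples. It changed no call of a named gene or list other than those given with their comparison.

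Some values turned sign. KLF1 in RNA was 0.001716 in protein-coding genes and -0.05548 to 0.04145 without a replicate, and IGF2BP2 in footprints -0.1541 to 0.08805. For efficiency, IGF2BP2 and ZBTB7A were -0.03885 and -0.02724 with RLE size factors, -0.03923 and -0.02769 with DESeq2, and -0.0337 and -0.0219 in protein-coding genes. HMGA2 was 0.003586 without globins, 0.001784 with no replicate block and 0.02899 with the crossed block, and IGF2BP1, fitted at 3.88, was -0.08248 with DESeq2. Leaving out a replicate gave HBA2 -0.1819 to 0.3306, BCL11A -0.1867 to 0.09796, LIN28B -0.6244 to 0.02192, IGF2BP2 -0.08789 to 0.1321, IGF2BP3 -0.5059 to 4.54, HMGA2 -0.2618 to 0.2894, ZBTB7A -0.2098 to 0.1594, MYB -0.2176 to 0.02883 and SOX6 -0.06353 to 0.4273. Within samples, HBG1 was 0.03104 with RLE size factors, 0.031 with DESeq2 and -0.08125 to 0.04361 without a replicate. LIN28B was 1.857 with DESeq2, which called it (adjusted p = 0.0317), and -0.3122 to 0.01096 without a replicate. IGF2BP1, fitted at -1.52, was 0.5 with DESeq2. Fits of LIN28B, IGF2BP1 and IGF2BP3 rest on adult counts near 0. Named genes kept direction and call in 1958 footprint, 1836 RNA, 525 efficiency and 1919 within-sample values. With direction kept, they lost a call in 17, 10, 49 and 13, and gained a call in 0, 5, 9 and 3. Values that turned sign, such as the LIN28B call within samples with DESeq2, are not among these.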

Other observations

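The metallothionein and immediate early gene lists, both tests of let-7 targets and the division of splits by how far they mixed the groups, were chosen after results had been seen. The p-values of these added lists come from the same data and are not independent evidence. Their bootstrap intervals resampled genes, so they measure spread between genes and not between samples.

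Metallothioneins, which bind zinc and copper, were lower in cord. All 8 tested in RNA were called lower, with a median log2 change of -2.98 (95% bootstrap interval -3.74 to -2.37, camera adjusted p = 2.69e-32, or p = 0.0018 with an estimated correlation). In footprints 5 of 5 were lower (median -3.02, interval -3.36 to -2.18, p = 1.12e-05 with an estimated correlation). Members of this family share reads. Immediate early genes, which respond within minutes to growth factors and stress, were higher in cord RNA in 15 of 23 cases and lower in 1 (median 1.06, interval 0.208 to 1.62, camera adjusted p = 1.01e-19, or p = 0.000241 with an estimated correlation), NR4A1, EGR3 and EGR2 having the smallest p. In footprints 11 of 19 were higher and 1 lower (median 0.762, interval 0.0463 to 1.41, p = 0.0064 with an estimated correlation).

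A hypothesis was that targets of let-7, the microRNA that LIN28B restrains, are higher where LIN28B is expressed. Without the key genes, the LIN28B and let-7 list had 14 of 28 members higher in cord RNA and 1 lower, with a median log2 change of 0.307 (interval 0.176 to 0.657) and a camera p of 6.59e-05 (0.00411 with an estimated correlation). In footprints 9 of 20 were higher and 1 lower (median 0.42, p = 0.000746, or 0.0103 with an estimated correlation). The first run used a smaller set of targets, of which 7 of 14 were higher and 1 lower in RNA (median 0.304, interval -0.0365 to 0.662, camera p = 0.011, or 0.0355 with an estimated correlation) and 4 of 10 higher and 1 lower in footprints (p = 0.0315, or 0.0658 with an estimated correlation). The whole list replaced it after that result had been seen. The whole list with its key genes had already been seen to be higher, so neither test is independent evidence. Origin and LIN28B level are confounded here, so any other difference between cord and adult cells could give the same, and the hypothesis stays open.

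Other splits of the samples were compared with the real split. For RNA, footprints and efficiency the real split was the only 1 of 35 with as many genes called (5214, 2113 and 60). The highest of the others was 0 in each. Within samples it was the only 1 of 40 (8321 against 1720). An arbitrary division of these samples is argued against for the RNA, footprint and efficiency counts. The within-sample comparison decides nothing, since its splits exchanged RNA and footprint libraries, which differ in kind whatever the samples. A chance difference between the sources of the cells is not excluded, since the replicates may be technical. For lists in footprints the real split was also the only 1 of 35 (18 lists against 17 at most in the others). That margin decides little, since leaving out a replicate gave 16 to 19 lists. In RNA 8 of 35 splits called as many as 12 lists (up to 19), in efficiency 5 of 35 called as many as 5 (up to 6), and within samples 3 of 40 called as many as 9 (up to 9). These splits kept most of the real contrast. The other splits that reached the real count in RNA (7) and efficiency (4) were all among the 16 that exchanged 1 sample of each origin, and those within samples exchanged the assays of 1 or 2 samples. The 18 splits that mixed both origins equally called up to 1 list in RNA, 0 in footprints and up to 2 in efficiency, and the 9 that exchanged 4 of 8 samples within samples up to 1. Such evenly mixed splits are too few for a share under 0.05 (18 or 9 beside the real one).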
